A study of Mus musculus with 18 samples.

How the data were processed

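Bulk poly(A) RNA sequencing was measured in 18 mouse samples in 3 groups of 6. The normal nerve samples were trigeminal nerves with floxed Nf1 and no Cre. The plexiform neurofibroma samples were trigeminal nerves with floxed Nf1 and a Cre driven by the Postn promoter. The MPNST (malignant peripheral nerve sheath tumour) samples came from animals with the same Cre in which Nf1 and Arf, an alternative product of the Cdkn2a locus, were both floxed; the labels give no body site for them. Per the labels' protocols, RNA was purified on columns and made into stranded libraries after poly(A) selection. Groups were taken from the labels, and every column of the table was matched to a sample by its name; 0 columns had no sample. Sample numbers are names only and pair nothing across groups.

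The deposited table holds estimated counts per gene, which need not be whole numbers, with no further normalization. Per the submitters' processing notes, Salmon 1.4.0, FastQC, DESeq2 and the mouse build GRCm39 were used. The annotation release, Salmon's settings, any trimming and how transcripts were summed to genes are not given in the sources used here. Salmon assigns reads to transcripts by estimation, so counts of gene families with near-identical members (H2, Ear, Amy, Try and Ifi genes, for example) and of overlapping genes are uncertain. The table has 51290 genes, and 0 rows lacked a gene name. No genome coordinates are reported, because the annotation at hand is of another build than the submitters'; it was used only for which genes neighbour each other.

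Counts were rounded to whole numbers. Totals per library ran from 14304163 to 20335502 counts in nerve, from 15308065 to 20056349 in neurofibroma and from 13885900 to 23652617 in MPNST. Counting error alone gives a relative standard error of 31.6% at 10 counts, 10.0% at 100 and 3.2% at 1000. The libraries carried no molecular identifiers that the labels mention, so every such error or floor covers counting error only. A gene at 0 in a whole group was given a floor of 3 counts over that group. CPM values, which scale each count by its library's total, were computed without further scaling, so ratios of CPM can differ from fitted log2 changes, which use TMM-scaled library sizes; the difference is large where a few genes take much of a library. No pair of columns was identical, and the lowest chi-square per degree of freedom between libraries of a group was 18.8, so no library was counted as a duplicate. Within-group Spearman correlations over 17446 genes ran from 0.67 to 0.95 in MPNST, from 0.94 to 0.98 in nerve and from 0.97 to 0.98 in neurofibroma.

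The following choices were made before the data were examined, except where an alternative is said to have been chosen later. Each comparison was fitted on its own pair of groups with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit and glmQLFTest, two-sided). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are given with their standard error (SE), and CPM as mean ± SD with n = 6 per group. Gene lists, 34 in number and written from textbook knowledge of nerve, Schwann cells, tumour pathways, immune cells and neighbouring tissues, held 577 entries, of which 576 were found (Rigi was not found). Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Member counts are given as adjusted over all genes tested and as adjusted over the list alone. List levels are means of log2(CPM + 1) over the list. A further 5 lists (salivary gland, pancreatic acinar cell, sympathoadrenal cell, pituitary, mature sympathetic and adrenal markers) were written after the libraries had been looked at. They serve to describe libraries and to name candidate sources, of which they are no independent test. Named genes followed a rule. It took Nf1, Cdkn2a and Postn; the 5 largest rises and 5 largest falls among called genes with an own symbol, at least 10 CPM in the higher group and no overlap between groups; the 2 members with the smallest p of each called list (for at most the 10 lists with the smallest p) and 1 member of every other list; and the leading member in the minority direction of a list with calls both ways. For genes called in both steps it took 5 per pair of directions. Other genes are said to have been chosen after their values were seen. A gene that this rule named is not reported here.

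Alternatives were other normalizations (RLE, upper quartile), other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, one fit of all 18 samples, an adjusted p below 0.01, glmTreat against a log2 change of 1, leaving out mitochondrially encoded genes, and leaving out each library in turn. Chosen after seeing the data were fits without the MPNST libraries 2 and 6, without 2, 3 and 6, without nerve library 6 and neurofibroma library 1, a robust fit, a minimum absolute log2 change of 1, and fits with or within 2 runs of columns in the table, a possible batch that no label names. Shares and totals were compared with exact two-sided permutation tests over 924 relabellings, whose smallest possible p is 0.00216. Splits of the samples were drawn 100 times per comparison. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

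The tests were tested on simulated data with the real means, library sizes and dispersions. For neurofibroma against nerve, edgeR recovered 69.1% of 97 genes changed 2-fold and 92.9% of 99 changed 4-fold among 16245 genes, with 10 unchanged genes called. For MPNST against neurofibroma it recovered 5% of 100 and 45.9% of 98 among 16243 genes, with 2 unchanged genes called, and for MPNST against nerve 1.02% of 98 and 41% of 100 among 16077 genes, with 1 unchanged gene called. A list of 30 genes changed 2-fold was called in each simulation, and 0 of 33 unchanged lists were called by camera. Each simulated gene was drawn independently of the others. The simulations therefore do not test camera on lists whose genes vary together. Real lists did so, with an estimated correlation of 0.94 for MHC class II genes in MPNST against nerve.

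The series design states that the 6 MPNST came from 6 mice. Nothing in the labels says whether the nerve and neurofibroma samples came from separate animals, so p-values there measure only the spread between these samples, which may be technical in part. Both groups hold libraries with Xist and libraries with Y-linked transcripts at 10 CPM or more, so neither group comes from 1 animal. The MPNST were new in this series, and the nerve and neurofibroma samples came from an earlier one, so series and group cannot be told apart in the comparisons with MPNST. The labels give no sequencing date, sex, age or pairing. The Nf1 and Arf alleles delete exons, and a count over the whole gene (for Cdkn2a, over the Arf and Ink4a transcripts together) can stay high after such a deletion, so these counts are no strict check of the genotypes.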

Results

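RNA was sequenced from 18 mouse samples to set malignant peripheral nerve sheath tumours (MPNST) beside plexiform neurofibromas, which are benign nerve tumours. The 6 normal nerve and 6 plexiform neurofibroma samples were trigeminal nerves with floxed Nf1, without and with a Cre recombinase under the Postn promoter. The 6 MPNST carried that Cre with floxed Nf1 and Arf. Nf1 encodes neurofibromin, a negative regulator of RAS, and Arf is a tumour suppressor transcribed from the Cdkn2a locus. Total estimated counts per library were 14304163 to 20335502 in nerve, 15308065 to 20056349 in neurofibroma and 13885900 to 23652617 in MPNST. Totals, the share of mitochondrially encoded genes and the share of the 10 highest genes did not differ between groups past the threshold in 9 exact two-sided permutation tests (lowest adjusted p = 0.399). The 10 highest genes took 17.53 ± 18.37% of counts in MPNST and 7.71 ± 0.9% in neurofibroma (n = 6 each), and MPNST library 2 alone reached 54.45%. The first principal component held 62.3% of the variance over the 2000 most variable genes.

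Nf1, the gene targeted in both tumour groups, averaged 123.4 ± 32.5 CPM in nerve, 81.8 ± 8.95 in neurofibroma and 60.3 ± 32.4 in MPNST (SD, n = 6 each). It fell in neurofibroma against nerve (log2 change -0.60, SE 0.16, adjusted p = 0.0304) and in MPNST against nerve (-0.82, SE 0.27, adjusted p = 0.026). Between MPNST and neurofibroma its log2 difference was -0.21 (SE 0.23, adjusted p = 0.478; -0.61 and 0.00952 with limma-voom). MPNST libraries 1 to 5 held 46.5, 28.1, 52.2, 58.6 and 53.4 CPM, below every neurofibroma library (66.7 to 91.3 CPM). Salivary gland transcripts lower the value of library 2. It was 52 CPM when the salivary gland list was left out, though that list does not hold all of the transcripts particular to this library. With TMM it was 72.2 CPM and within the neurofibroma range (63.6 to 86.7 CPM), while libraries 1, 3, 4 and 5 stayed below it. The library labelled MPNST 6 held 122.8 CPM, above every neurofibroma library and within the range of nerve (82.4 to 160.7 CPM). Its Nf1 was thus unlike that of the other libraries of its group, but a whole-gene count cannot contradict a label. The call in neurofibroma was lost on leaving out nerve library 3, 4 or 5 or neurofibroma library 1, 2, 4 or 5 (adjusted p from 0.0504 to 0.0664), while the log2 change stayed at -0.53 to -0.63. It was also lost in the fit of all 18 samples (-0.58, adjusted p = 0.531). The call in MPNST against nerve was lost without MPNST library 1 (0.0535) or 4 (0.0521) or nerve library 3 (0.0506) or 4 (0.0567), with log2 changes of -0.71 to -0.78.

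Cdkn2a, which also encodes the cell cycle inhibitor Ink4a, rose from 1.09 ± 0.989 CPM in nerve to 5.34 ± 1.85 in neurofibroma (log2 change 2.27, SE 0.47, adjusted p = 0.0101; 2.90 without nerve library 1). In MPNST it averaged 120.9 ± 279.8 CPM: library 4 held 692.0 CPM, libraries 1, 2, 3 and 5 held 10.7, 1.44, 9.76 and 11.3, and the library labelled MPNST 6 held 0.314. Its rise in MPNST against neurofibroma was 4.46 (SE 1.49, adjusted p = 0.0305). This was 0.54 without MPNST library 4 (adjusted p = 0.529), and the call was also lost on leaving out any 1 neurofibroma library (0.0525 to 0.0636). Against nerve the rise was 6.73 (SE 1.73, adjusted p = 0.00803). It was 2.82 without MPNST library 4 (adjusted p = 0.0165) and 7.33 without nerve library 1 (adjusted p = 0.0135). Postn, the matrix protein gene whose promoter drives the Cre, rose at each step, from 21.3 ± 6.54 to 161.4 ± 68.6 and 1968 ± 1645 CPM. The log2 changes were 2.92 (SE 0.31, adjusted p = 0.00106) and 3.73 (SE 0.62, adjusted p = 0.00082). Its lowest MPNST values were 223.9 CPM in library 2 and 342.1 CPM in the library labelled MPNST 6. These counts cover whole genes and do not read the deleted exons, so they are no strict check of the genotypes.

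**Figure D1:**
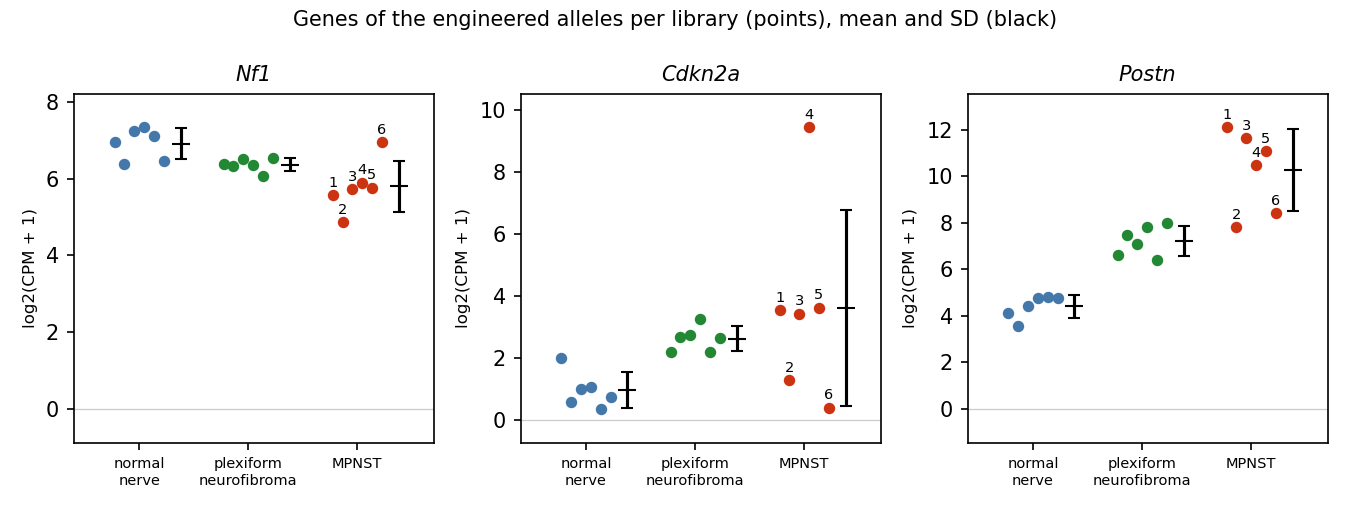
Levels of Nf1, Cdkn2a and Postn in each library as log2(CPM + 1) on the vertical axis, with the 3 groups along the horizontal axis, MPNST libraries numbered, and the group mean and SD in black (n = 6 each). The library labelled MPNST 6 lies highest of its group for Nf1 (122.8 CPM), library 4 lies highest for Cdkn2a (692.0 CPM), and Postn steps up from nerve to neurofibroma to MPNST.

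Several libraries held transcripts of tissues other than nerve or nerve tumour. In MPNST library 2, a salivary gland list written after the libraries had been looked at took 45.9% of all counts, against at most 0.118% in any other library. Bpifa2 alone, a secreted salivary protein gene, stood there at 235219 CPM. Skeletal muscle genes took 6.49% of counts in MPNST library 3, where the muscle actin gene Acta1 reached 11429 CPM. The library labelled MPNST 6 held 0.939% of counts in sympathoadrenal genes and 0.598% in pancreatic acinar genes, both lists also written afterwards. The catecholamine synthesis gene Th stood there at 1736 CPM and the pancreatic protease gene Ctrb1 at 1190 CPM, each at most 0.772 CPM in the other 5. MPNST library 1 was highest of its group in the B and plasma cell list (mean log2(CPM + 1) of 6.94, next 2.43). Neurofibroma library 1 was high in skeletal muscle (5.88, next 0.64) and adipocyte genes (5.17, next 1.26), and nerve library 6 in oligodendrocyte and astrocyte genes (5.99).

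**Figure D2:**
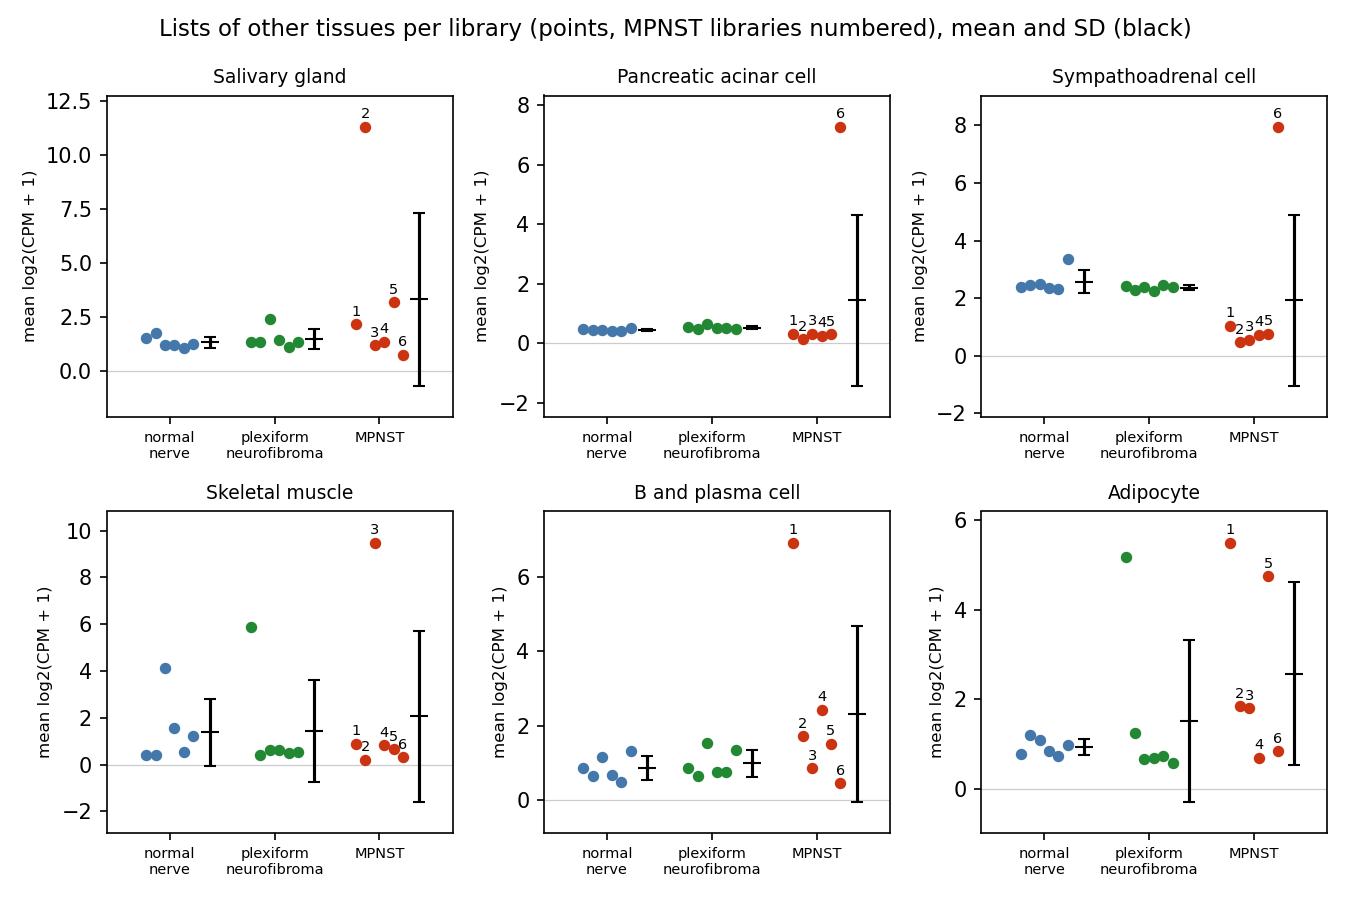
Mean log2(CPM + 1) of 6 gene lists for other tissues and cell types in each library, with the 3 groups along the horizontal axis and MPNST libraries numbered. Library 2 stands apart for salivary gland (11.33), library 3 for skeletal muscle (9.49), the library labelled MPNST 6 for pancreatic acinar (7.29) and sympathoadrenal cells (7.96), and library 1 for B and plasma cells (6.94).

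The first comparison set plexiform neurofibroma against normal nerve, which differ by label in the Cre. Largest changes are given here and below among called genes with a name of their own, a mean of at least 10 CPM in one group and no overlap between groups. Within these limits Pmp2, a lipid-binding protein of peripheral myelin, rose most, from 6.94 ± 4.3 to 179.8 ± 69.8 CPM (log2 change 4.70, SE 0.56, adjusted p = 0.00166, edgeR, n = 6 each). It was followed by the serine protease gene Klk8 (3.47, SE 0.49), the interferon-induced Ifi27l2a (3.08, SE 0.47), the acyl-CoA thioesterase gene Them5 (3.08, SE 0.42) and Postn. Falls were smaller. Lancl3 went from 20.4 ± 5.01 to 7.92 ± 3.89 CPM (-1.38, SE 0.30, adjusted p = 0.0125).

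Lists of matrix, myelin, Schwann lineage and RAS-MAPK output genes were called higher in neurofibroma by camera and not with an estimated correlation, and outside the matrix list most members were not called. Of 25 extracellular matrix genes 17 rose and 8 were not called (19 rose when adjusted over the list alone). The collagen crosslinking enzyme gene Lox rose by 1.96 (SE 0.25). The list had a camera adjusted p of 4.91e-17, and adjusted p = 0.299 with an estimated correlation. Among 18 myelin genes 6 rose (9 over the list alone), with Gldn, which helps assemble nodes of Ranvier, at 1.58 (SE 0.31). Camera gave 5.49e-09, and adjusted p = 0.444 with an estimated correlation. Schwann lineage genes rose in 4 of 18 (7 over the list alone), with S100b from 861.0 ± 97.2 to 1511 ± 170.4 CPM and the neural crest factor Foxd3 at 1.25 (SE 0.24). RAS-MAPK output genes rose in 8 of 17 (10 rose and 1 fell over the list alone), among them Dusp6, a phosphatase induced by ERK (0.85, SE 0.11), and Emp1 (1.87, SE 0.23). Camera gave 0.000668 for the Schwann and 7.81e-07 for the RAS-MAPK list, both with adjusted p = 0.299 with an estimated correlation. Mesenchymal transcription factors rose in 6 of 18 (8 over the list alone; camera 0.000499, adjusted p = 0.504 with an estimated correlation). The homeobox genes Meox1 (2.35, SE 0.44) and Meox2 (2.26, SE 0.41) led this list. Cholesterol synthesis genes rose in 6 of 20 (7 over the list alone; camera 6.88e-05, adjusted p = 0.444 with an estimated correlation). The rises were small, 0.49 (SE 0.08) for Nsdhl and 0.63 (SE 0.12) for Mvd.

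Among the immune lists, 4 were called in neurofibroma, interferon response, macrophage and both MHC classes. Interferon response genes rose in 10 of 21 (15 over the list alone), among them the antiviral gene Ifit1 (1.49, SE 0.26) and Isg15 (1.87, SE 0.40). Macrophage genes rose in 7 of 18 (14 rose and 1 fell over the list alone), with the osteopontin gene Spp1 at 1.58 (SE 0.27) and Ms4a7 at 1.98 (SE 0.45). MHC class II genes rose in 3 of 9 (3 over the list alone), with the peptide-loading genes H2-DMb1 at 1.30 (SE 0.31) and H2-DMb2 at 2.81 (SE 0.66). Camera gave 5.49e-09, 3.15e-07 and 0.00048 for these lists, each with adjusted p = 0.444 with an estimated correlation. MHC class I presentation genes rose in 3 of 11 (6 over the list alone; camera 0.000499, adjusted p = 0.504 with an estimated correlation), with the immunoproteasome gene Psmb10 at 0.83 (SE 0.19). H2-K1, a class I molecule, stood at 179.2 ± 48.3 against 81.8 ± 42.1 CPM (1.14, SE 0.29, adjusted p = 0.0237). It lost its call without nerve library 4 (0.0509) or neurofibroma library 2 (0.0549), 4 (0.0587) or 6 (0.0569). Neurofibroma library 6 was the highest of its group for Ifit1 and library 2 for Psmb10.

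Other lists were not called by camera. Their called members stand beside 1307 genes called higher and 988 lower by edgeR among all 16464 tested. Of 21 sensory neuron genes 1 fell, the synaptic gene Snap25 (-0.45, SE 0.11), at a camera adjusted p of 0.0802. This list passed, lower, without nerve library 3 (0.0458) or 6 (0.000184) or neurofibroma library 5 (0.0166), and nerve library 6 held the lowest level of its group (8.17, next 8.78). Endothelial genes had 15 of 15 not called (0.101). They passed, lower, without nerve library 4 (0.0166) or 5 (0.0175) or neurofibroma library 1 (0.0498) or 2 (0.0226). Erythroid genes (6 not called, 0.111) passed, lower, without nerve library 3 (0.0458) or 5 (0.029) or neurofibroma library 5 (0.0484). Nerve fibroblast and perineurium genes held 4 rises and 1 fall in 17 (0.101, and 0.0425 without nerve library 3), among them the apolipoprotein gene Apod (1.61, SE 0.26) and Lgi2 (-0.67, SE 0.12). The 3 cytotoxic and NK cell genes were not called (0.135, and 0.0312 without nerve library 3). Cell cycle genes rose in 3 of 30 (0.143), with the thymidylate synthase gene Tyms at 0.99 (SE 0.23). Receptor tyrosine kinases and ligands held 5 rises, Axl among them (1.37, SE 0.20), and 1 fall in 22 (0.247).

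Single calls stood in further lists whose camera adjusted p ran from 0.271 to 0.842. They were Cspg4 (1.82, SE 0.25) among 11 pericyte and smooth muscle genes, Ezh2 (1.18, SE 0.27) among 11 PRC2 components and Nr4a1 (0.74, SE 0.16) among 17 dissection and stress genes. Of 19 p53 targets 2 rose, Phlda3 among them (0.85, SE 0.16), and Zmat3 fell (-0.58, SE 0.12). Of 17 hypoxia genes 2 rose, Adm among them (1.33, SE 0.31), and 1 fell. Dendritic cell genes held 1 rise and 1 fall in 9 (0.835). The 3 adipocyte and 8 skeletal muscle genes tested were not called (0.959 and 0.835), with neurofibroma library 1 far above its group in both. Nor were the tested T cell, B and plasma cell, mast cell, neutrophil, immune checkpoint, Hox, oligodendrocyte and astrocyte, epithelium and sex chromosome genes, whose lists had adjusted p from 0.271 to 0.98. Median, mean and test differed in sign for p53 targets (median -0.06, mean 0.01, test up) and hypoxia (-0.05, 0.07, down). They also differed for adipocyte (0.04, 0.05, down) and sex chromosome genes (0.25, 0.33, down). Adjusted over the list alone, rises and falls numbered 5 and 1 in nerve fibroblast and perineurium, 7 and 2 in receptor tyrosine kinase, 2 and 2 in hypoxia and 2 and 1 in dendritic cell genes. They numbered 1 and 0 in both cell cycle and cytotoxic and NK cell genes and 0 and 1 in erythroid genes, and the counts of the other lists without a camera call stayed as given.

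By edgeR, 2295 of 16464 genes were called, 1307 higher and 988 lower, and 442 of them had an absolute log2 change of at least 1 (381 higher, 61 lower). The majority turned with a filter of at least 1 CPM in 6 samples, with 1197 genes higher and 1298 lower. Some of the named calls were lost on leaving out 1 library. Of the largest falls within the limits above, Trank1 (-2.16, SE 0.65), Zdbf2 (-1.86, SE 0.51) and Nova2 (-1.29, SE 0.37) had their highest values in nerve library 6 (76.9, 38.8 and 53 CPM). Without that library their log2 changes were -0.80, -0.93 and -0.69. The call of Trank1 was lost without nerve library 4 (adjusted p = 0.0503) or any neurofibroma library (0.0656 to 0.085), that of Zdbf2 without neurofibroma libraries 2 to 6 (0.0565 to 0.065), and that of Nova2 without any neurofibroma library (0.0551 to 0.0765). Among minority members, the receptor gene Ret (-0.53, SE 0.15) lost its call without nerve libraries 2 to 5 or neurofibroma libraries 1, 2, 4 or 6 (0.0542 to 0.0739). Flt3 (-0.38, SE 0.11) lost its call without nerve libraries 2 to 5 or neurofibroma libraries 1, 2, 3, 4 or 6 (0.0553 to 0.0866). Vegfa (-0.41, SE 0.12) lost its call without nerve library 3 or 5 or neurofibroma library 1 or 2 (0.0515 to 0.0695). Siglech (1.68, SE 0.49) lost its call without nerve libraries 1 to 5 or neurofibroma libraries 1, 4, 5 or 6 (0.0542 to 0.0853), and was at 2.34 without nerve library 6. The count was 1147 without neurofibroma library 4, 1355 without 2 and 1471 without 6, 1404 without nerve library 5 and 3817 without nerve library 6. A single fit of all 18 samples, which shares the spread of the MPNST with the other groups, called 2 genes, Akr1b3 and Corin (named after their values were seen). Without nerve library 6 and neurofibroma library 1, left out after seeing the data, 3421 genes were called, of which 2068 were shared. Within 2 runs of columns in the table, a possible batch that no label names and that was tried after seeing the data, each group had 3 libraries. EdgeR called 0 genes in the first run (3002 at an unadjusted p below 0.05) and 5 in the second (2796 at an unadjusted p below 0.05). The 5 were Akr1b3, Gm8730, H2-D1, Lama4 and Rarres2, named after their values were seen, and no other tool was run within the runs.

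The second comparison, for which the series was set up, set MPNST against plexiform neurofibroma. Within the same limits sensory neuron genes fell furthest. Both trigeminal groups held neuron transcripts at high levels, with a sensory neuron list level of 8.77 in nerve and 8.62 in neurofibroma, against 1.89 in MPNST. In both comparisons with MPNST, malignancy and the tissue sampled therefore cannot be told apart as sources of the neural falls. The same holds for the rises in these comparisons, those of matrix, immune and vessel genes included. The sodium channel gene Scn10a went from 529.5 ± 116.2 to 0.351 ± 0.416 CPM (log2 change -10.34, SE 0.72, adjusted p = 2.5e-06, edgeR, n = 6 each), the neuropeptide gene Calca from 598.6 ± 118.0 to 1.21 ± 0.998 CPM (-8.83, SE 0.54). The receptor gene Mrgprd changed by -10.21 (SE 0.55) and Ppp1r1c by -10.11 (SE 0.74). Pou4f3, a sensory transcription factor gene at 19.6 ± 3.58 CPM in neurofibroma, had 0 counts in all 6 libraries labelled MPNST and was at least 729.3-fold lower. The cold receptor gene Trpm8 was at 72.5 ± 12.5 CPM in neurofibroma and was seen in 1 MPNST library, at 0.0702 CPM. The largest rises within these limits were Ear2, an eosinophil-associated ribonuclease (7.72, SE 1.20), the cartilage matrix gene Cilp (7.09, SE 1.13), the chemokine gene Ccl8 (6.78, SE 1.02) and Doc2b (6.45, SE 1.07). The matrix gene Tnc went from 4.75 ± 1.87 to 333.7 ± 275.6 CPM (6.31, SE 0.66, adjusted p = 3.88e-05). Doc2b was highest in the library labelled MPNST 6 (243.5 CPM). Without that library its rise was 5.18, and without MPNST library 5 the rises of Ear2 and Ccl8 were 6.74 and 6.05. Without MPNST library 1 the log2 changes of Scn10a, Mrgprd and Ppp1r1c were -11.01, -10.80 and -10.88.

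Neural and glial lists fell. Of 21 sensory neuron genes 14 fell (15 over the list alone; camera adjusted p = 7.01e-14, and adjusted p = 0.245 with an estimated correlation). The library labelled MPNST 6 had a list level of 5.38 against at most 1.44 in the other 5. There the member Snap25 stood at 639.2 CPM, while Scn10a (0.105 CPM), Scn11a (0.105 CPM) and Calca (0.367 CPM) stayed low. Of 18 myelin genes 15 fell (15 over the list alone; camera 7.49e-11, adjusted p = 0.358 with an estimated correlation). Pmp22, a compact myelin protein, went from 3853 ± 746.0 to 133.6 ± 115.7 CPM and Drp2, of the Schwann cell membrane, changed by -6.01 (SE 0.62). Schwann lineage genes fell in 6 of 18 (5 over the list alone; camera 0.000374, adjusted p = 0.566 with an estimated correlation). They included S100b, from 1511 ± 170.4 to 19.7 ± 29 CPM, and the signalling gene Shh (-7.44, SE 0.98). Without MPNST library 1 the log2 changes of Drp2, S100b and Shh were -6.75, -7.12 and -9.83. Oligodendrocyte and astrocyte genes fell in 7 of 11 (7 over the list alone; camera 0.000374, adjusted p = 0.487 with an estimated correlation), with Olig2 at -6.07 (SE 0.91), and -5.24 without neurofibroma library 1. Cholesterol synthesis genes fell in 15 of 20 (17 over the list alone; camera 2.45e-10, adjusted p = 0.358 with an estimated correlation). Nsdhl was at -2.08 (SE 0.20), and Msmo1 went from 205.3 ± 26.6 to 32.6 ± 20.9 CPM.

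Proliferation and matrix genes rose. Of 33 cell cycle genes 32 rose (32 over the list alone; camera 8.1e-12, adjusted p = 0.618 with an estimated correlation). The topoisomerase gene Top2a went from 3.98 ± 1.54 to 157.4 ± 162.7 CPM, and Tyms rose by 2.67 (SE 0.26). The log2 change of Top2a was 4.64 without the library labelled MPNST 6. The list level was 1.97 ± 0.13 in neurofibroma and 4.3 ± 1.72 in MPNST, from 1.6 in library 2 to 6.49 in the library labelled MPNST 6. With TMM, which offsets the salivary transcripts of library 2, it was 2.54 there and above every neurofibroma library. Of 25 extracellular matrix genes 19 rose (19 over the list alone; camera 2.08e-05, adjusted p = 0.776 with an estimated correlation), the collagen crosslinking enzyme gene Loxl2 by 3.19 (SE 0.38). The matrix list level was raised in 4 MPNST libraries (8.21 to 9.23, against 5.59 to 6.82 in neurofibroma) but not in library 2 (5.18, and 6.49 with TMM) or the library labelled MPNST 6 (6.03). PRC2 components, which methylate histones, held 7 rises and 1 fall in 11 (7 and 1 over the list alone; camera 0.0183, adjusted p = 0.245 with an estimated correlation). The catalytic subunit gene Ezh2 rose by 2.35 (SE 0.39) and Eed by 1.37 (SE 0.16). The alternative subunit gene Ezh1 fell (-0.73, SE 0.23, adjusted p = 0.0225, and 0.0582 without MPNST library 5). Mesenchymal transcription factors rose in 9 of 20 (9 over the list alone; camera 0.0388, adjusted p = 0.869 with an estimated correlation), led by Prrx1 (3.85, SE 0.86, and 2.92 without MPNST library 4). This list call was lost without MPNST library 1 (0.0676), 3 (0.0733), 4 (0.0558) or 5 (0.0716) or neurofibroma library 5 (0.0542). With TMM the mesenchymal list level was 3.61 to 4.84 in MPNST libraries 1 to 5. It was 1.58 in the library labelled MPNST 6, below every neurofibroma library (2.49 to 3.22).

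Immune and vessel genes rose in part. Macrophage genes rose in 15 of 19 (16 over the list alone; camera 0.000929, adjusted p = 0.776 with an estimated correlation). The macrophage list level ran from 3.25 to 6.69 in MPNST and from 3.44 to 4.34 in neurofibroma. On this scale, which is without TMM, not every MPNST library was raised. The lysozyme gene Lyz2 went from 87.3 ± 37.8 to 707.0 ± 637.3 CPM. It stood at 125.1 CPM in MPNST library 2 and 111.8 CPM in the library labelled MPNST 6, within the neurofibroma range (45.5 to 144.5 CPM, without TMM). TMM offset 1.36 log2 units in library 2, so its Lyz2 level is not shown to stay within that range once scaled. Folr2 rose by 4.55 (SE 0.67, and 5.14 without neurofibroma library 1). Immune checkpoint genes rose in 7 of 8 (7 over the list alone; camera 0.0397, adjusted p = 0.776 with an estimated correlation), with Lag3 at 2.88 (SE 0.55). The checkpoint call was lost without MPNST library 1 (0.0843), 4 (0.0619) or 5 (0.0735) or neurofibroma library 3 (0.0527). Endothelial genes rose in 7 of 15 (11 over the list alone; camera 0.0265, adjusted p = 0.869 with an estimated correlation), with Eng at 2.33 (SE 0.48) and the junction gene Cdh5 at 2.26 (SE 0.49). The endothelial call was lost without MPNST library 1 (0.0843), 3 (0.0733) or 5 (0.0541).

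Lists not called by camera still held called members. Of all 16537 genes tested here edgeR called 4176 higher and 2772 lower, so called members alone do not set a list apart. MHC class II genes rose in 7 of 10, H2-Eb1 by 3.58 (SE 0.87), at an adjusted p of 0.0551. The list passed without MPNST library 2 (0.0434) or 3 (0.0306), the library labelled MPNST 6 (0.00938) or neurofibroma library 6 (0.0464). MPNST libraries 1 and 5 held its highest levels (8.25 and 8.11), and H2-Eb1 was at 2.96 without library 5. RAS-MAPK output rose in 7 of 17 (0.104, and 0.0325 without MPNST library 2), Emp1 by 3.72 (SE 0.67). Of 19 p53 targets 8 rose, Mdm2 by 0.97 (SE 0.19), and 2 fell (0.159). Dissection and stress genes rose in 7 of 17 (0.0725, and 0.027 without MPNST library 2 or 0.0444 without the library labelled MPNST 6), Ier2 by 2.36 (SE 0.22), and Hsph1 fell (-1.47, SE 0.38). B and plasma cell genes, in which MPNST library 1 stood apart, rose in 5 of 6 (0.159), with Cd22 at 4.81 (SE 1.07), and 3.24 without that library. T cell genes rose in 7 of 9 (0.233), with Trac at 4.58 (SE 1.13), and dendritic cell genes in 6 of 10 (0.202), with Itgax at 4.94 (SE 0.82). Trac was at 2.99 without MPNST library 1 and Itgax at 4.22 without library 5. Rises numbered 2 of 7 in neutrophil (0.372), 3 of 11 in pericyte and smooth muscle (0.393) and 4 of 21 in interferon response genes (0.606). Cytotoxic and NK cell genes rose in 4 of 5 (0.202, and 0.0249 without the library labelled MPNST 6) and class I presentation genes in 1 of 11 (0.202, and 0.0409 without that library).

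Among the remaining lists, Hox genes held 3 rises and the fall of Hoxd1 (-8.54, SE 0.74, and -9.29 without MPNST library 3) in 5 tested (0.666, and 0.0341 without MPNST library 2). Nerve fibroblast and perineurium genes held 8 rises and 2 falls in 18 (0.759), Lgi2 at -3.58 (SE 0.35). Hypoxia genes held 3 rises and 3 falls in 18 (0.606), Ndrg1 at -3.20 (SE 0.50). Receptor tyrosine kinases and ligands held 5 rises and 3 falls in 22 (0.877), and the test pointed down with a median of 0.31 and a mean of 0.43. Mast cell genes rose in 1 of 9 (0.576) and epithelium genes in 3 of 6 (0.759). Of 5 adipocyte genes 1 fell, Cidea (-4.30, SE 0.78), while the list (0.759) pointed up with a median log2 change of 1.82. The adipocyte list level ran from 0.7 to 5.5 in MPNST (median 1.83) and from 0.59 to 5.17 in neurofibroma (median 0.72). Epcam, an epithelial adhesion gene, had a log2 change of 6.20 (adjusted p = 0.0164). It was 2.81 (adjusted p = 0.066) without MPNST library 2, the library with salivary transcripts, and 7.51 without neurofibroma library 3. The 5 erythroid (0.799, median 0.03, mean -0.14, test down), 5 sex chromosome (0.807) and 9 skeletal muscle genes (0.735) tested were not called. Actn3, of fast muscle fibres, stood at 2311 CPM in MPNST library 3 and at most 2.45 CPM in the other 5. Its log2 change went from 5.35 (adjusted p = 0.0976) to -3.45 without that library (adjusted p = 0.0409). Adjusted over the list alone, rises numbered 8 in MHC class II, 6 in B and plasma cell, 4 in epithelium, 2 in pericyte and smooth muscle and 0 in class I presentation genes. Rises and falls numbered 7 and 2 in dissection and stress, 6 and 1 in dendritic cell, 4 and 1 in Hox, 9 and 3 in nerve fibroblast and 4 and 1 in receptor tyrosine kinase genes, and the counts of the other lists without a camera call stayed as given.

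By edgeR, 6948 of 16537 genes were called, 4176 higher and 2772 lower, and 5268 of them had an absolute log2 change of at least 1. Without MPNST libraries 2 and 6, left out after seeing the data, 10234 genes were called (5306 higher, 4928 lower). Of these 6629 were shared with the first count, 3 of them in the opposite direction, and without 2, 3 and 6 the count was 11247. Within the 2 runs of columns 4375 genes (2002 higher, 2373 lower) and 1473 genes (517 higher, 956 lower) were called, so the majority was lower there. With limma-voom, which weights libraries by quality, 48.3% of 9747 calls were higher against 60.1% here. All MPNST came from another series than the neurofibromas, and their body site is not given.

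The third comparison set MPNST against normal nerve and spans both steps. Within the same limits falls were again led by sensory neuron genes, among them Scn10a (log2 change -10.60, SE 0.79) and Mrgprd (-10.55, SE 0.52). The sodium channel gene Scn11a went from 314.5 ± 81 to 0.233 ± 0.251 CPM (-10.17, SE 0.72, adjusted p = 3.63e-06, edgeR, n = 6 each). Pou4f3 and Iqschfp had 0 counts in all 6 libraries labelled MPNST and were at least 825.6-fold and 468.5-fold lower, and Trpm8 stood at 88.5 ± 29.6 CPM in nerve. The largest rise within these limits was the haptoglobin gene Hp, from 0.224 ± 0.144 to 112.9 ± 136.7 CPM (9.87, SE 1.89). It was followed by Cilp (7.17, SE 1.13), the replication factor gene Pclaf (7.10, SE 1.17), Tnc (7.03, SE 0.70, adjusted p = 2.5e-05) and Ear2 (6.89, SE 1.34). Pclaf was highest in the library labelled MPNST 6 (138.4 CPM) and Hp in MPNST library 2 (316.2 CPM), and without these libraries the rises were 6.14 and 8.21. Hp was uneven over the group, at 115.2 and 237.9 CPM in MPNST libraries 1 and 5. In libraries 3 and 4 Hp was at 3.58 and 3.61 CPM, and in the library labelled MPNST 6 at 0.838 CPM. Ear2 was at 5.81 without MPNST library 5 and 7.61 without nerve library 3, and Scn10a at -11.27 without MPNST library 1.

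Neural and glial lists fell here too. Of 21 sensory neuron genes 15 fell (15 over the list alone; camera adjusted p = 6.77e-14, and adjusted p = 0.316 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 20 (15 over the list alone; camera 1.39e-07) and myelin genes in 12 of 18 (13 over the list alone; camera 2.88e-07), both with adjusted p = 0.608 with an estimated correlation. Fdft1, of sterol synthesis, went from 178.1 ± 12.1 to 33.3 ± 22.3 CPM, and the periaxin gene Prx was at -5.35 (SE 0.75). Schwann lineage genes fell in 5 of 17 (4 over the list alone; camera 0.0159) and oligodendrocyte genes in 5 of 7 (5 over the list alone; camera 0.0346), both with adjusted p = 0.668 with an estimated correlation. Both calls were lost without the library labelled MPNST 6 (0.0578 and 0.0995). S100b was at -5.34 (SE 0.87) and Shh at -7.30 (SE 0.98). Without MPNST library 1 Prx, S100b and Shh were at -6.16, -6.32 and -9.67.

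Rises were most numerous in cell cycle genes, 31 of 32 (31 over the list alone; camera 8.33e-12), and extracellular matrix genes, 21 of 25 (22 over the list alone; camera 1.32e-09). RAS-MAPK output genes rose in 10 of 17 (10 over the list alone; camera 0.0143). Each of these lists had adjusted p = 0.608 with an estimated correlation. The matrix list level was lowest in MPNST library 2 (5.18) and the library labelled MPNST 6 (6.03), against 3.78 to 5.63 in nerve. The replication helicase gene Mcm3 rose by 4.12 (SE 0.46), Loxl2 by 4.33 (SE 0.40), Emp1 by 5.58 (SE 0.74) and Dusp6 by 2.52 (SE 0.34). Macrophage genes rose in 15 of 19 (17 over the list alone; camera 2.77e-05), mesenchymal transcription factors in 12 of 20 (14 over the list alone; camera 0.00529) and immune checkpoints in 6 of 7 (6 over the list alone; camera 0.0341, and 0.0584 without MPNST library 1). Each of these had adjusted p = 0.668 with an estimated correlation. The macrophage list level ran from 3.25 to 6.69 in MPNST and from 2.27 to 3.59 in nerve. For mesenchymal factors it ran from 1.71 to 5.04 and from 1.73 to 3.12, so without TMM neither was raised in every MPNST library. The complement gene C1qb rose by 3.83 (SE 0.68), the epithelial-mesenchymal transition factor genes Snai1 by 3.44 (SE 0.66, and 2.75 without MPNST library 4) and Snai2 by 3.24 (SE 0.63), and Cd276 by 2.44 (SE 0.47). PRC2 components held 7 rises, Eed by 1.63 (SE 0.17), and the fall of Ezh1 (-0.75, SE 0.24) in 11 (7 and 1 over the list alone). Camera gave 0.023 for them, with adjusted p = 0.316 with an estimated correlation, and the call was lost without the library labelled MPNST 6 (0.0578).

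MHC class II genes rose in 10 of 10 (10 over the list alone; camera 0.0143, adjusted p = 0.752 with an estimated correlation). H2-Aa went from 48.1 ± 33.3 to 816.3 ± 938.1 CPM, with its lowest MPNST value, 24.5 CPM, in the library labelled MPNST 6. Class I presentation genes rose in 7 of 11 (9 over the list alone; camera 0.035, adjusted p = 0.811 with an estimated correlation), and the call was lost without MPNST library 1 (0.0929), 2 (0.0635) or 5 (0.0639). Interferon response genes rose in 9 of 21 (10 over the list alone; camera 0.0369, adjusted p = 0.849 with an estimated correlation), with Irf7 at 3.22 (SE 0.69). The interferon call was lost without MPNST library 1 (0.146) or 5 (0.0909), and Irf7 was at 2.55 without library 5.

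The member counts below stand beside 4527 genes called higher and 3007 lower by edgeR among all 16384 tested. Called members alone thus do not set a list apart. Lists without a camera call included dissection and stress response, with 10 rises and 2 falls in 17 (adjusted p = 0.0658). It passed without MPNST library 2 (0.0289) or 4 (0.0413) or nerve library 6 (0.0356). Endothelial genes held 6 rises and 1 fall in 15 (0.135, and 0.0403 without MPNST library 4). Cytotoxic and NK cell genes rose in 3 of 4 (0.14), and passed without nerve library 3, 4, 5 or 6 or the library labelled MPNST 6 (0.0268 to 0.0491). Rises numbered 5 of 6 in B and plasma cell (0.135), 5 of 10 in dendritic cell (0.165), 4 of 6 in T cell (0.555) and 4 of 12 in pericyte and smooth muscle genes (0.324). They numbered 3 of 6 in neutrophil (0.38) and 3 of 5 in epithelium genes (0.885). Of 19 p53 targets 8 rose, the death receptor gene Eda2r by 5.99 (SE 1.29, and 4.09 without MPNST library 3), and 2 fell, Zmat3 at -1.42 (SE 0.32) among them (0.232). Calls in both directions also stood in nerve fibroblast genes (6 and 2 in 18; 0.584), receptor tyrosine kinases (6 and 3 in 22; 0.857), mast cell (1 and 1 in 9; 0.407) and adipocyte genes (2 and 1 in 4; 0.837). Hox genes held 3 rises and 1 fall in 5 (0.906), and camera pointed up and fry down. Hypoxia genes held 4 rises and 6 falls in 18 (0.682), with a median of -0.35, a mean of 0.07 and a test pointing down. The 5 erythroid (0.407) and 5 sex chromosome genes (0.857) were not called. Of 10 skeletal muscle genes 1 was called, Actn3 (7.65, SE 2.60, adjusted p = 0.0305; list 0.682). Its log2 change was -1.13 without MPNST library 3 (adjusted p = 0.317), and its call was lost without nerve library 1, 2, 4, 5 or 6 (0.0578 to 0.0632). Without nerve library 3 it was at 8.76. Adjusted over the list alone, rises and falls numbered 10 and 3 in dissection and stress, 6 and 0 in B and plasma cell, 4 and 0 in cytotoxic and NK cell, 1 and 0 in mast cell, 6 and 1 in receptor tyrosine kinase and 0 and 0 in skeletal muscle genes. The counts of the other lists without a camera call stayed as given.

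By edgeR, 7534 of 16384 genes were called, 4527 higher and 3007 lower, and 5966 of them had an absolute log2 change of at least 1. Without MPNST libraries 2 and 6, left out after seeing the data, 10419 genes were called (5650 higher, 4769 lower). Of these 7229 were shared with the first count, 1 of them in the opposite direction, and without 2, 3 and 6 the count was 11118. Within the 2 runs of columns 5107 genes (2271 higher, 2836 lower) and 1136 genes (352 higher, 784 lower) were called, so the majority was lower there too. With limma-voom, 49.5% of 10382 calls were higher against 60.1% here.

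**Figure D3:**
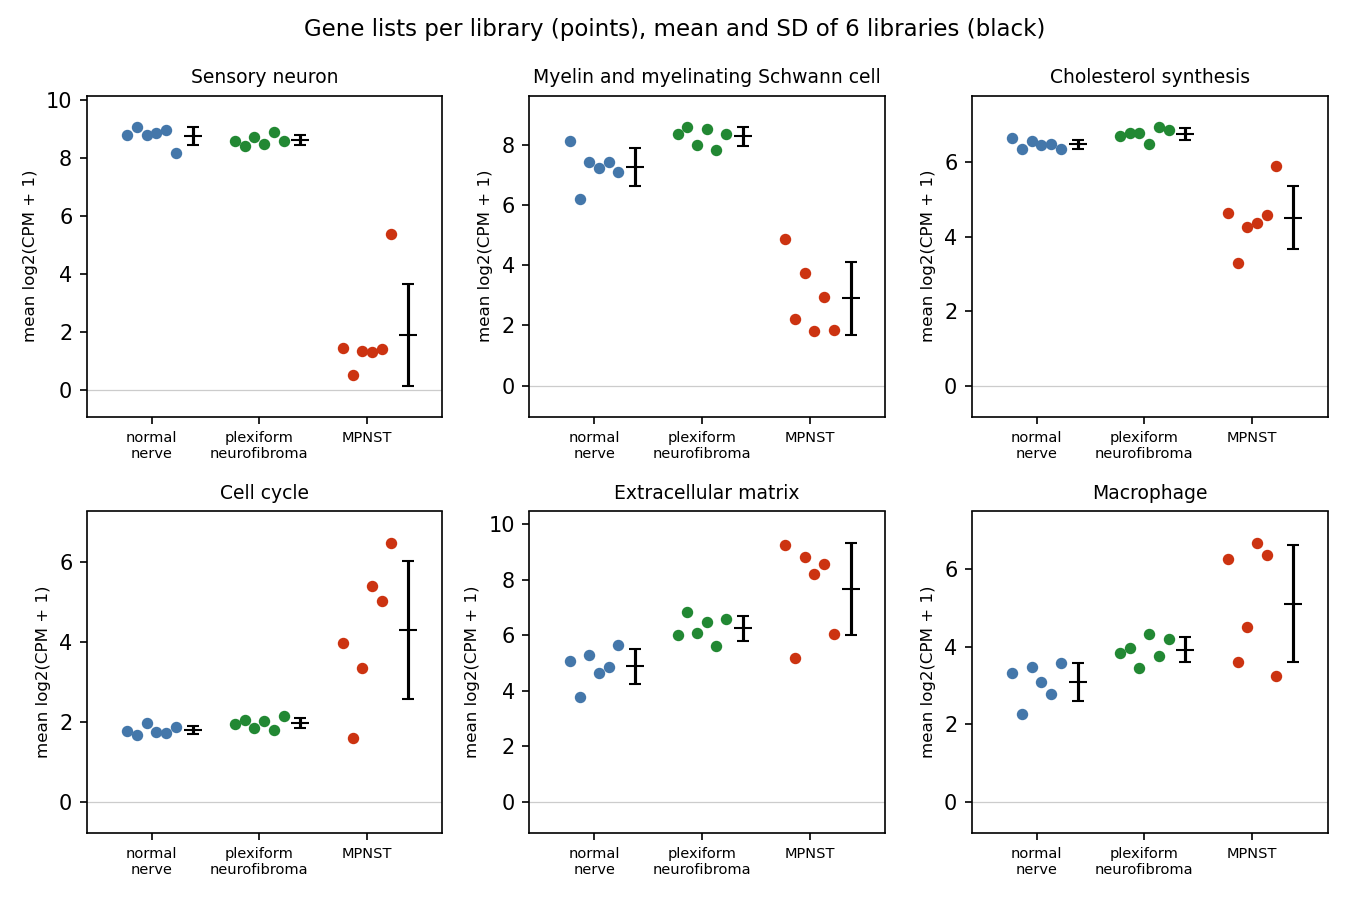
Mean log2(CPM + 1) of 6 gene lists fixed beforehand in each library, with the 3 groups along the horizontal axis and the group mean and SD in black (n = 6 each). Sensory neuron genes stood at 8.77 in nerve, 8.62 in neurofibroma and 1.89 in MPNST, myelin genes at 7.25, 8.27 and 2.9, and cell cycle genes at 1.79, 1.97 and 4.3.

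Some changes from nerve to neurofibroma went on in MPNST and others turned. Of 16033 genes tested in both steps, 461 rose in both, as Postn did, against 314.9 from independent lists. Examples were the receptor gene Pilra (2.60, SE 0.32, then 3.02, SE 0.51), the protease inhibitor gene Timp1 (2.26, SE 0.42, then 3.46, SE 0.64), Nkd2 (2.24, SE 0.29, then 2.19, SE 0.56) and Cdkn2a, whose second rise rested on MPNST library 4. A fall in both steps was called for 305 genes (independent lists 168.9). Among them were the calcium-binding protein gene Calb1 (-1.05, then -6.83), Rusc2 (-1.17, then -1.92), Mapk4 (-1.02, then -2.56) and Etnppl (-1.20, then -5.91). A rise and then a fall was called for 155 genes (independent lists 225.7), but with DESeq2 for 287, above its independent value of 249.9. Pmp2 stood at 6.94, 179.8 and 4.92 CPM in the 3 groups and Cnmd at 11.7, 47.2 and 0.0945 CPM, and the pair of log2 changes was 3.08 and -7.89 for Them5, 2.09 and -7.03 for Otop1 and 1.90 and -3.40 for Egfl8. A fall and then a rise was called for 107 genes (independent lists 235.6). They included the kinase gene Sik1 (-1.40, then 2.31), Als2cl (-1.40, then 2.51), Tpbg (-1.21, then 3.64), Zbtb16 (-1.17, then 2.94) and Impa2 (-1.13, then 1.45). Myelin, Schwann lineage and cholesterol synthesis genes were called as lists in opposite directions in the 2 steps, with the estimated-correlation values given above.

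Both steps share the neurofibroma libraries, whose chance values enter the 2 changes with opposite sign. In 10 simulations of unchanged groups, where no group differed by construction, edgeR called 0 genes in both steps. All 18 libraries were drawn with the dispersion of neurofibroma against nerve, although the MPNST libraries spread more. The covariance of the 2 log2 changes was -0.0431 there and 0.16 in the data, a difference of 0.203 (correlations -0.50 and 0.16). The simulated correlation depends on that dispersion and is no fair match for that of the data. With DESeq2, over 32047 genes, the sign turned, with a covariance of -0.20 and a correlation of -0.09, so the sign depends on the tool or the genes tested. With the neurofibroma libraries split so that each step used 3 of them, the covariance was 0.256 and 0.108. The number of genes called in both steps, 1028 in full, was 14 and 32 in these splits, near the 14.4 and 28.9 of independent lists (945.2 in full). It was 1550 without MPNST libraries 2 and 6, left out after seeing the data, and 2 in the fit of all 18 samples (Akr1b3 and Corin).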

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

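The tests of salivary gland RNA, of a normal adrenal gland or ganglion and of pancreatic RNA were chosen after the result was seen. So were the added gene lists and the values on CPM without TMM. High members of an added list in a library already looked at therefore describe that library and are no independent test of a source. The tests of a wrong label, another kind of tumour and a copy gain had their bounds written before their values were seen. In each group of 6 libraries, the gap between the most extreme library and the nearest of the others was divided by the range of the group, on the log2(CPM + 1) scale for genes and list means. A ratio above Dixon's 95% limit marked a library far from the others. Chance marks about 1 in 20 groups, and 57 of 531 groups (10.7%) were marked here.

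MPNST library 2 stood far above the other 5 in the share of its 10 highest genes (ratio 0.82; 54.45%, next 15.18%) and in Perp (0.75; 6.88, next 1.90). It stood far below them in p53 targets (0.64; 3.16, next 3.97), dissection and stress genes (0.68; 2.93, next 4.60), Eed (0.64), Loxl2 (0.80; 3.19, next 6.15), Ier2 (0.64; 3.48, next 4.85), Sik1 (0.75; 2.67, next 4.96) and Rusc2 (0.74; 1.72, next 4.28). These levels are CPM without TMM, and the salivary gland list alone lowers every other gene of this library by 0.89 log2 units there; with TMM its p53 target level, 4.29, lay within the range of the other 5 (3.77 to 4.49). All 17 detected genes of the salivary gland list, of which 4 reached 10 CPM in nerve or neurofibroma, lay at least 1 log2 unit above the highest other MPNST library, led by Bpifa2 (235219 CPM), Amy1 (100863) and Smr3a (38427), so salivary gland RNA is a candidate source. A gland sample with a wrong label and no tumour RNA was not excluded: over 3181 genes raised in MPNST without this library, its median excess over neurofibroma was 1.08 log2 units, 63% of that of the other 5 (1.71) and above the bound of 50% written beforehand, but only 28.3% on CPM without TMM and without the genes of the added lists. That second scaling leaves part of the dilution in place. The list holds 17 genes, while 29 genes stood above 1000 CPM in library 2 and at most 1 CPM in MPNST libraries 3 and 4 and the library labelled MPNST 6. TMM offset 1.36 log2 units in library 2, against 0.89 for the list, so the 28.3% may be too low. The cell cycle level of library 2 with TMM, 2.54, was the lowest of the 6 (next 3.44) though above every neurofibroma library. No salivary gland library was compared, so how many of these genes a gland itself expresses, and whether any tumour RNA is there, stays open. The design names no biological difference for a single library, and none was tested.

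The library labelled MPNST 6 stood far above the other 5 in the sensory neuron list (ratio 0.81; 5.38, next 1.44), Trank1 (0.98; 4.69, next 0.08), Zdbf2 (0.89; 7.77, next 0.94), Ret (0.74; 10.15, next 3.49), Snap25 (0.81; 9.32, next 2.18) and Mapk4 (0.77; 3.62, next 1.04). The members Scn10a and Scn11a (0.105 CPM each) and Calca (0.367 CPM) of the sensory neuron list were low there. The list level thus rests on other members, among them Snap25 (639.2 CPM). Of 22 sympathoadrenal genes, 21 lay at least 1 log2 unit above the highest other MPNST library (median difference 7.27). Of the 22, 7 reached 10 CPM in nerve or neurofibroma. Th stood at 1736, Mycn at 351.3 and Alk at 230.3 CPM in this library. A normal adrenal medulla or sympathetic ganglion in place of a tumour was argued against, since its cell cycle list level of 6.49 was 1.10 above the next MPNST library. Another kind of tumour in place of an MPNST stays open. Over 3640 genes raised in MPNST without this library, its median excess over neurofibroma was 0.18, against 1.59 in the other 5 (lowest 1.24). This was 11.5% of theirs and within the bound of 20% written beforehand, but 21.1% on CPM without TMM and the added lists. Its Nf1 level was above every neurofibroma library, but a whole-gene count is no strict check of the genotype and cannot decide this. Pancreatic acinar RNA is a candidate source of part of its transcripts, since all 17 detected genes of that list, none at 10 CPM in nerve or neurofibroma, lay at least 1 log2 unit above the highest other library, led by Ctrb1 (1190 CPM), Amy2a5 (684.3) and Cpb1 (523.8). Normal ganglion RNA in addition to a tumour was not tested and stays open, and no biological explanation was tested.

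MPNST library 4 stood far above the other 5 in Cdkn2a (ratio 0.64; 9.44, next 3.62). The neighbouring genes Cdkn2b (299.2 CPM, next 24.8) and Mtap (306.7 CPM, next 78.7) were also highest there. A copy gain reaching the 10 nearest expressed genes on each side could not be decided: their median excess was 0.49 log2 units, above the bound written beforehand, but its place at the 92.6th percentile of 14910 windows of 20 genes fell short of the percentile asked for. Of the 20 neighbours 14 lay above 0, and the nearest 6 had a median excess of 0.63. The nearest on each side, Gm49890 and Dmrta1, were at 2.69 and 4.63. The next outward, Klhl9 and Elavl2, were at 0.66 and -2.04. These genes were named after their values were seen. A narrower gain and a change in regulation of the locus cannot be told apart from a wider gain, because the counts carry no copy number. No biological explanation was tested.

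MPNST library 3 lay far above its group in the skeletal muscle list (ratio 0.93; 9.49, next 0.88), Actn3 (0.84; 11.17, next 1.79), Abcc9 (0.63; 6.90, next 4.43) and Trpm8 (a ratio of 1), for which it was the single library with any count, and far below it in Impa2 (0.72; 2.01, next 3.59). MPNST library 1 lay far above its group in the B and plasma cell list (0.69; 6.94, next 2.43), Shh (0.83; 0.60, next 0.10) and Ppp1r1c (0.65; 0.80, next 0.28).

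Nerve library 6 lay far below the other nerves in the sensory neuron list (ratio 0.68; 8.17, next 8.78), Scn10a (0.75; 8.02, next 9.24), Scn11a (0.72; 7.36, next 8.29), Calca (0.66; 8.12, next 8.88), Pou4f3 (0.69; 3.68, next 4.48) and Ret (0.73; 8.83, next 9.36). It lay far above them in the epithelium list (0.75; 1.34, next 1.09), the dissection and stress list (0.66; 4.45, next 4.06), Trank1 (0.85; 6.28, next 3.34), Zdbf2 (0.85; 5.32), Nova2 (0.80; 5.75, next 3.97), Doc2b (0.73; 4.46, next 1.59) and Olig2 (0.71; 4.31, next 1.31). Nerve library 3 lay far above the others in skeletal muscle (0.69; 4.13, next 1.54), cytotoxic and NK cell genes (0.69; 0.68, next 0.30) and Ccl8 (0.74; 1.65, next 0.48). Nerve library 2 lay far below them in RAS-MAPK output (0.79; 3.15, next 3.59) and Meox2 (0.64; 0.48, next 1.47).

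Neurofibroma library 1 lay far above its group in the skeletal muscle (ratio 0.96; 5.88, next 0.64) and adipocyte lists (0.85; 5.17, next 1.26), Actn3 (0.79; 5.89, next 2.27), Lipe (0.82; 5.09, next 3.27), Cidea (0.73; 4.65, next 3.52) and Hp (0.82; 4.93, next 0.94). Library 3 of this group lay far above it in the epithelium list (0.73; 2.14, next 1.31) and Epcam (0.66; 2.39, next 0.86), and far below it in Havcr2 (0.65; 0.94, next 1.59). Library 6 was far above in Ighm (0.74; 5.52, next 3.94), Ifit1 (0.78; 6.15, next 5.38) and Irf7 (0.69; 4.08, next 3.38), library 2 in Psmb10 (0.70; 5.91, next 5.16) and Cldn5 (0.63; 4.72, next 4.20), and library 5 far below in Pmp2 (0.79; 5.57, next 7.46).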

How the results depend on the processing

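The tests without doubted libraries, with or within runs of columns, with a robust fit or with a minimum log2 change were chosen after the data had been seen; the others were planned. No paired analysis was possible because the sample numbers are names only and no label ties animals across groups. Direction was compared only where the original or the alternative value passed the threshold. The causes of the differences below were not tested, except where fewer samples, more genes tested or a stricter threshold explain them by construction.

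For neurofibroma against nerve, 2295 genes were called. RLE or upper-quartile scaling, a filter of 1 CPM in 6 samples, no mitochondrially encoded genes, a robust fit and the run covariate gave 1908 to 2495, and leaving out nerve library 6 with neurofibroma library 1 gave 3421. The count was 1438 with no filter on low counts (33221 genes tested), 3533 with DESeq2 (2283 shared), 4026 with limma-voom (2251 shared) and 2 in the fit of all 18 samples (Akr1b3 and Corin; 1343 at an unadjusted p below 0.05). It was 520 at an adjusted p below 0.01, 13 with glmTreat, 442 with an absolute log2 change of at least 1, and 0 and 5 within the runs of columns (edgeR, 3002 and 2796 at an unadjusted p below 0.05). Leaving out 1 library gave 1147 to 3817.

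For MPNST against neurofibroma, 6948 genes were called. The other settings gave 5268 to 10234, and beyond 1.5 times lay 4063 at an adjusted p below 0.01, 2472 with glmTreat, 4375 and 1473 within the runs, and 11247 without MPNST libraries 2, 3 and 6. Leaving out 1 library gave 5899 to 9123. For MPNST against nerve, 7534 genes were called. The other settings gave 5107 to 11118, and beyond 1.5 times lay 4633 at an adjusted p below 0.01, 3125 with glmTreat and 1136 within the second run. Leaving out 1 library gave 6508 to 9447. Scaling moved the median of all genes by at most 0.08 log2 units.

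Of the 1028 genes called in both steps, 461 rose in both, 155 rose then fell, 107 fell then rose and 305 fell in both. DESeq2 called 1676 (287 rising then falling, where independent lists give 249.9, 189 falling then rising, 548 falling in both). The fit of all 18 samples called 2, both rising then falling, with 0 in each other pair of directions. At an adjusted p below 0.01 there were 144, namely 85, 32, 2 (Gm42713 and Sik1) and 25 in that order. With neurofibroma libraries 1 to 3 in the first step there were 14, namely 5 (Emp1, Gm2000, Pilra, Postn and Rpl10a), 6, 0 and 3 (Ccdc85a, Habp4 and Wnk1). With libraries 4 to 6 first there were 32, namely 15, 9, 1 (Sik1) and 7. Genes behind counts of 5 or fewer are named after their values were seen. Without MPNST libraries 2 and 6 there were 1550 (593 falling in both), and without 2, 3 and 6 there were 1626 (632).

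Among named genes under each alternative, 1215 values stayed on the same side of the threshold for neurofibroma against nerve, called or not, 114 lost a call (45 in the fit of all 18 samples) and 20 gained one. The figures were 1374, 30 and 5 for MPNST against neurofibroma and 1431, 43 and 4 for MPNST against nerve. Actn3 changed direction. Against neurofibroma its log2 change without MPNST library 3 was -3.45 (edgeR adjusted p = 0.0409; 0.0409 to 0.162 on leaving out 1 library, and 0.0409 to 0.922 over all its alternatives). Against nerve it was -1.13 without that library (adjusted p = 0.317) and -0.95 without libraries 2, 3 and 6 (0.44; 0.0191 to 0.317 on leaving out 1 library, and 0.0112 to 0.606 over all its alternatives); library 3 holds the skeletal muscle transcripts. For gene lists, 517, 521 and 526 values stayed on the same side of the threshold, called or not, 11, 28 and 33 lost a call and 16, 29 and 19 gained one in the 3 comparisons, and with an estimated correlation each of the 10, 12 and 15 list calls was lost. With fry, which asks whether the genes of a list move one way and not how they stand against other genes, 1, 3 and 3 of these calls were lost: MHC class I (adjusted p = 0.058) in neurofibroma against nerve, macrophage (0.0542), endothelium (0.144) and mesenchymal factors (0.131) in MPNST against neurofibroma, and MHC class II (0.0634), class I (0.0986) and interferon response (0.181) in MPNST against nerve. It gained nerve fibroblast (0.0177), cytotoxic and NK cell (0.0458) and cell cycle (0.0458) in the first, dissection and stress (0.0339), RAS-MAPK output (0.0455) and p53 targets (0.00179) in the second, and dissection and stress (0.0144) and p53 targets (0.00413) in the third.

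In 100 splits of the 12 libraries of each comparison, the real split included, 1 called as many genes as the real one each time, which was the real split itself. A random split of these libraries thus rarely gave as many gene calls. The splits cannot tell what sets the groups apart, since any systematic difference, such as series in the comparisons with MPNST, would rank first too. The highest other counts were 1, 2627 and 3818. For list calls the splits do not exclude chance and cannot measure it. At least as many lists as the real 10, 12 and 15 were called in 38, 72 and 46 of 100 splits. The highest other counts were 18, 25 and 24. A split that mixes the groups unequally can carry part of a group difference, so these tallies draw no line for chance.

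Depth limits low genes most, with a counting error of 31.6% at 10 counts, and in MPNST library 2 the salivary gland list left fewer counts for all others. In simulations edgeR recovered 69.1% of 2-fold changes for neurofibroma against nerve, but 5% for MPNST against neurofibroma and 1.02% for MPNST against nerve, so a gene not called there is not shown to be unchanged.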

Other observations

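The lists for pituitary and for mature sympathetic and adrenal markers, the counts of Hox genes, the check of runs of columns and the test of carry-over were tests chosen after the result was seen. The MPNST libraries differed from each other in genes of body position. Hox genes, which pattern the body axis, stood above 1 CPM for 20, 1, 15, 7, 23 and 4 of 39 members in MPNST libraries 1 to 6, against 2 to 5 in each nerve and neurofibroma library. Hoxd1 was the highest member in all 12 nerve and neurofibroma libraries. In MPNST the highest was Hoxc8 in library 1, Hoxb4 in library 3 and Hoxd8 in libraries 2, 4 and 5 and the library labelled MPNST 6. In MPNST library 4, Spp1 (osteopontin, a member of the macrophage list) stood at 11501 CPM and Dmp1 (dentin matrix protein) at 1452 CPM, where the next MPNST library held 311.0 and 2.32 CPM. These 2 genes were named after their values were seen, and no list of such genes was tested. That library also had the highest level of RAS-MAPK output of the group (6.24). MHC class II genes were highest in MPNST libraries 1 and 5 (8.25 and 8.11).

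Xist stood at 10 CPM or more, with 4 Y-linked genes below 10 CPM together (at most 0.27), in 3 nerve, 3 neurofibroma and 3 MPNST libraries. The Y-linked genes stood at 10 CPM or more, with Xist below 10 CPM (at most 3.6), in 3, 3 and 2. MPNST library 4 held both, with Xist at 18.5 CPM and the 4 Y-linked genes at 238.3 CPM together. No group was formed from these values. Pituitary genes had list levels of 1.65, 1.22 and 1.45 in nerve libraries 3, 5 and 6 and 1.01 in neurofibroma library 6, with group means of 0.93 ± 0.59 in nerve, 0.29 ± 0.36 in neurofibroma and 0.12 ± 0.12 in MPNST (SD, n = 6 each). Of these 8 genes 2 reached 10 CPM in nerve. Mature sympathetic and adrenal markers stood at 6.37 in the library labelled MPNST 6 (0.336% of counts), 4.68 in nerve library 6, 3.37 ± 0.64 over the nerves and 3.06 ± 0.12 over the neurofibromas, and 5 of the 10 reached 10 CPM in nerve or neurofibroma. Neurofibroma library 3 held the odorant-binding protein gene Obp1a at 791.2 CPM.

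The columns of the table form 2 runs, which no label explains. The spread between the runs was equalled or exceeded in 6812 of 8000 assignments of all 18 libraries (exact one-sided permutation p = 0.852) and in 300 of 400 assignments of the nerve and neurofibroma libraries (exact one-sided permutation p = 0.75).

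MPNST library 5 held small amounts of the salivary transcripts of library 2, with Bpifa2 at 179.0 CPM and Amy1 at 91.8 CPM. As a hypothesis, these may be carry-over of RNA, library or reads from library 2. The log2 ratio of library 5 to library 2 was taken over 29 genes above 1000 CPM in library 2. These held at most 1 CPM in MPNST libraries 3 and 4 and the library labelled MPNST 6. The ratio had an SD of 0.34 at a median of 0.0891%, as a single source would give. MPNST library 1 held these genes at a median of 0.0078% (SD 1.20), at most 3.54 CPM. Neurofibroma library 3 held 0.118% of counts in the salivary gland list, against 0.0513% in MPNST library 5, and was not put through this test. A small admixture of the same gland would keep one ratio as well, so it stays open beside carry-over.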
